A study of Danio rerio with 39 samples.

How the data were processed

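RNA of whole young adult male zebrafish and of embryo pools was hybridised to Agilent zebrafish oligonucleotide arrays, 2 channels per array, with Cy5 on the sample and Cy3 on the reference in all 39 arrays per the labels. The reference of the acute arrays was a mixture of the adult RNA samples of the study, healthy and infected, that of the embryo arrays a mixture of embryo infection samples, and that of each chronic array a control fish. No dye was swapped, so a probe's dye bias cancels between groups on one reference and stays in the chronic ratios. The labels give a mean RNA integrity number of 9.5 and a minimum of 8.9 for adult samples. Each adult array held a different fish per the labels, and embryo infections were made on separate days.

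The deposited scanner files of the 18 acute arrays and of 6 embryo arrays hold the mean intensity of each spot and the median intensity of its local background, from Agilent Feature Extraction 9.5.3.1 (acute) and 9.1.3.1 (embryo) per the file headers. They also hold a log10 ratio of Cy5 over Cy3 that Feature Extraction computed after background subtraction and dye normalization, per the file headers. The authors' deposited value table has a column of log2 ratios for each array. In the acute columns it equals the scanner log10 ratio put on the log2 scale, with a largest difference of 5.7e-05. The embryo columns correlated across probes with the 6 scanner files at 0.969 to 0.992 but were not equal to them. The processing they come from is not given in the sources used here. The submitters' processing notes name Agilent Feature Extraction 9.5.3. For the chronic columns the log2 scale and the direction, infected over control, were taken from the labels and the spread of the deposited values and could not be checked against scanner files; their dye normalization is not given in the sources used here. Column medians were 0.017 to 0.143 in acute arrays, -0.0166 to 0.0167 in chronic arrays and -0.0369 to 0 in embryo arrays, and no column was centred further. The array of E11 pool C at 24 hpi had an SD of 1.54 over all probes, and 15.7% of its values were exactly 0.

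For the acute arrays, intensities were background-corrected with normexp (offset 50) on all spots. Control spots had weight 0 in the loess normalization within each array and were then left out, and spots marked as outliers were left out. Of 43370 probes, 39705 were well above background in Cy5 on at least 3 acute arrays and were tested, and 3665 were not; 1 of the tested probes had no usable value in Mma20 fish of 6 dpi, which leaves 39704 there. The chronic, embryo and chronic against acute comparisons used the deposited log2 ratios of all 43370 probes. No columns held the same values, and 0 columns of the table lacked a sample.

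Models were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and the package data.table (version 1.17.8), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All tests were two-sided. The 18 acute arrays were fitted together with 1 mean per group, the 4 chronic arrays against 0, and the 17 embryo arrays together; chronic against acute responses came from 1 fit of the 22 adult arrays. All 6 PBS fish served as controls on both days. The interaction is the change of Mma20 fish from 1 to 6 dpi minus that of E11 fish. Adult probe groups of at least 2-fold change were tested in the embryos with camera (preset correlation 0.01, and an estimated correlation). For comparisons that share the PBS fish, 20 data sets with no group changed were simulated, with drawn values for the 6 PBS fish too. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

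The procedure was tested on simulated data with 200 changed probes, 50 at each size. For Mma20 against PBS at 6 dpi, 16%, 62%, 94% and 100% of the probes changed by 0.5, 1, 2 and 3 on the log2 scale were recovered, with 4 false calls. For Mma20 against E11 at 6 dpi the shares were 2%, 52%, 92% and 98% (11 false calls), for the interaction 4%, 22%, 88% and 96% (5 false calls), for chronic infection 0%, 2%, 74% and 92% (4 false calls) and for chronic infection against the Mma20 response 0%, 10%, 68% and 88% (12 false calls). In embryos they were 0%, 0%, 22% and 52% at 2 hpi (4 false calls), 0%, 2%, 36% and 66% at 24 hpi (1 false call) and 0%, 0%, 22% and 74% at 120 hpi (5 false calls).

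Per the file headers, the acute arrays lay on 5 slides, each scanned once. PBS fish 1 to 4 were on slide 5 and fish 5 and 6 on slide 6. Slide 7 held E11 fish 1 to 3 of 1 dpi and fish 4 of 6 dpi, slide 8 E11 fish 5 and 6 of 6 dpi and Mma20 fish 1 and 2 of 1 dpi, and slide 9 Mma20 fish 3 of 1 dpi and fish 4 to 6 of 6 dpi. No slide held both groups of a comparison with PBS or between the strains on 1 day, so these have no value within a slide. Slides 7 and 9 each held fish of both days of 1 strain, and the days were also compared within them, with 1 mean per group and slide and the spread pooled over the 18 arrays, which takes a lone fish to vary like the others. The alternatives were the ratio of Feature Extraction, median centring with no loess, no background correction, the deposited table, no filter on dim probes, the slide as a random block, the replicate number as a block, PBS fish chosen by number, fits of the compared groups alone, array weights for the chronic arrays, and each array left out in turn. The slide as a fixed block among the 12 infected fish, the days compared within a slide and the Cy5 channel alone were added after seeing the data. So were the subtraction of mean acute ratios, 2 embryo arrays left out together and an embryo block for arrays with a scanner file. The other choices were made before the data were examined. The Cy5 channel alone stands for its log2 signal after the loess step and Aquantile normalization between arrays. Both steps also use the Cy3 signal.

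The files do not pair probes with genes. The rule fixed for named genes, the 8 highest and 8 lowest fold changes with a gene symbol, could therefore not be followed as written. The probes chosen instead are the 2 with the highest and the 2 with the lowest log2 fold change past the threshold in each comparison. Where none passed, they are the 2 with the lowest p-values. Not all of the chosen probes are named in the text. Those of chronic infection against the acute responses are left out. For the embryos the second probe is named only at 120 hpi. In the interaction the probes are those named in the comparisons with PBS, and the named probes followed into another comparison were chosen after their values were seen. The 33 gene lists fixed in advance and their 1-probe-per-gene alternative could not be tested. All 6 PBS fish are labelled 1 dpi, and 2 of the 3 PBS pools of 120 hpi carry a conflicting time of 2 h in 1 label; title and source name placed them. The design text speaks of 3 embryo infections, and a pool C of E11 at 2 hpi was not analysed here.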

Results

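Gene expression was measured in zebrafish (Danio rerio) infected with Mycobacterium marinum, a relative of the tuberculosis bacterium that causes tuberculosis in fish. The study asked how specific the host response is to the bacterial strain, to the stage of disease and to the life stage of the fish. RNA of whole adult males was compared on 22 oligonucleotide arrays and RNA of whole embryos on 17. In the acute experiment, approximately 10000 bacteria of strain Mma20, which is known to cause acute disease, or of strain E11, which is known for a slower course, were injected into the abdomen. Mma20 and E11 groups held 3 fish each at 1 day post infection (dpi) and 3 fish each at 6 dpi, and 6 fish given phosphate-buffered saline (PBS) were the controls. All 6 PBS fish are labelled 1 dpi although the design text has 3 fish per group on each day, so the day of the PBS fish stays open. Each acute sample was labelled with Cy5 and hybridised against Cy3-labelled RNA pooled from the adult fish of the study. In the chronic experiment, 4 arrays each set 1 fish with overt tuberculosis (Cy5) against 1 healthy control fish (Cy3). The design text gives E11 as the strain of the chronic infection and accounts for 3 infected fish, while the labels name 4. Embryos received approximately 50 colony-forming units of E11 or PBS into the caudal vein, and pools of 15 to 20 embryos were collected 2, 24 and 120 h after injection (hpi). Each embryo group held 3 pools, except E11 at 2 hpi with 2.

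Between 75.9% and 88.8% of the probes on an acute array lay well above background in the sample channel. The log2 ratios of arrays within a group correlated across probes at 0.659 to 0.877 in the acute experiment, 0.469 to 0.62 among the chronic arrays and 0.148 to 0.93 in embryos. Probes are not independent replicates, and precision was limited by the number of arrays. The 3 Mma20 fish of 6 dpi lay at 113 to 131 on the first principal component of the acute arrays, which held 34.2% of the variance. PBS fish lay at -35.4 to -27.4 on it, E11 fish of 6 dpi at -42.9 to -23.1, E11 fish of 1 dpi at -32.9 to -21.4 and Mma20 fish of 1 dpi at -12 to 7.76. On the second component, with 12.4% of the variance, PBS fish lay at 28.6 to 52.1 and all infected fish below them. Mma20 fish lay at -3.61 to 10.6 at 6 dpi and -22.9 to -6.52 at 1 dpi. E11 fish lay at -62.1 to -31.1 at 6 dpi and -35.9 to -13.3 at 1 dpi. PBS and infected fish shared no slide, so slides and infection cannot be told apart there. The files do not pair probes with genes, so features are given by probe identifier, and no gene list could be tested.

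Fish infected with Mma20 differed from PBS fish on 33.3% of the probes tested at 6 dpi. The highest fold change of the ratio was on probe A_15_P102047, with the sequence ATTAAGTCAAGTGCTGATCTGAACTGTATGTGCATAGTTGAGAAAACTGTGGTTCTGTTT. Its log2 ratio to the reference was 4.54 ± 0.23 (SD, n = 3) in Mma20 fish and -4.29 ± 0.79 (SD, n = 6) in PBS fish, a log2 fold change of 8.84 (SE 0.66, limma adjusted p = 5.82e-08). Probe LOLS11403, with the sequence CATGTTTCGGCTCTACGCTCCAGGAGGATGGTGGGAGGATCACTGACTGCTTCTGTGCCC, rose from -2.79 ± 0.69 (SD, n = 6) to 4.34 ± 0.80 (SD, n = 3), a log2 fold change of 7.13 (SE 0.61, limma adjusted p = 2.74e-07). The lowest fold change was on A_15_P114293 (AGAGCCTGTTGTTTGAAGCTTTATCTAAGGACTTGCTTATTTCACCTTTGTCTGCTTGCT), which went from -0.36 ± 0.53 (SD, n = 6) in PBS fish to -7.37 ± 0.89 (SD, n = 3), a log2 fold change of -7.02 (SE 0.56, limma adjusted p = 1.16e-07). Probe LOLS02339 (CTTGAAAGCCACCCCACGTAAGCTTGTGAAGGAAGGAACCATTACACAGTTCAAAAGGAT) followed with a log2 fold change of -5.96 (SE 0.46, limma adjusted p = 9.45e-08). On each of these 4 probes, all 3 Mma20 fish lay beyond all 6 PBS fish.

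In the same comparison, 13219 of 39704 probes passed an adjusted p of 0.05 in limma, 7663 of them higher and 5556 lower in Mma20 fish. At least 2-fold changes were found for 3213 probes that rose and 1904 that fell, and at least 4-fold changes for 804 and 339. With arrays centred on their medians and no loess step, the share of higher probes was 71.1% instead of 58.0%, and with the ratio of Feature Extraction it was 49.0%. PBS and infected fish shared no slide, so the comparisons with PBS have no value within a slide or with the slide as a fixed block. On A_15_P102047 the mean raw Cy3 signal of the reference was 50060 on PBS arrays and 3887 on Mma20 arrays of 6 dpi, so part of the change of its ratio lay in the reference signal. The reference held the same RNA on every acute array, and why its signal fell on this probe was not tested. The Cy5 channel alone gave a log2 change of 5.41, below the 6.27 of LOLS11403 and the 6.13 of A_15_P111645. Whether the Cy5 channel understates the change of A_15_P102047 stays open.

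**Figure D1:**
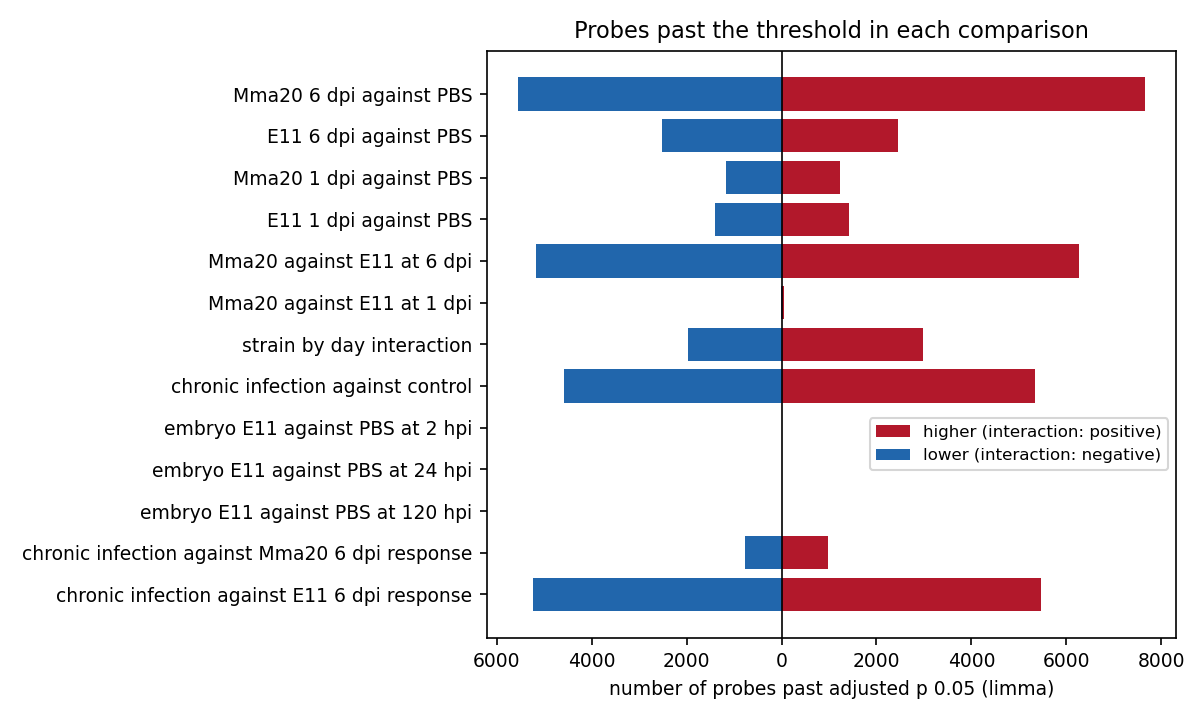
Number of probes past an adjusted p of 0.05 in limma in each comparison, with probes higher in the first group named to the right of 0 and lower to the left, and for the interaction positive and negative values. The Mma20 comparison with PBS at 6 dpi has 7663 probes on the right and 5556 on the left, and the 3 embryo comparisons have 0.

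E11 fish of 6 dpi differed from PBS fish on fewer probes and by smaller amounts. Probe LOLS11685 rose from -1.44 ± 0.47 (SD, n = 6) in PBS fish to 3.15 ± 0.35 (SD, n = 3), a log2 fold change of 4.59 (SE 0.32, limma adjusted p = 7.69e-07); it was well above background in 5 of the 6 PBS fish. Probe LOLS11542 rose by a log2 fold change of 3.77 (SE 0.87, limma adjusted p = 0.00927) and was well above background in 3 of the 6 PBS fish. Probe LOLS15965, with the sequence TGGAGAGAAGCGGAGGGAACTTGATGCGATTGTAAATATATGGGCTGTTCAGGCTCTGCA, fell from -0.31 ± 0.73 (SD, n = 6) to -4.52 ± 0.48 (SD, n = 3), a log2 fold change of -4.21 (SE 0.40, limma adjusted p = 8.17e-06). Probe A_15_P116757 fell by 2.72 on the log2 scale (SE 0.77, limma adjusted p = 0.029), and 2 of the 3 E11 fish lay below every PBS fish. Its log2 fold change was -1.99 without E11 fish 4 (limma adjusted p = 0.153) and -1.74 without E11 fish 6 (limma adjusted p = 0.186). Without PBS fish 3 it was -2.64 (limma adjusted p = 0.0502). That of LOLS11542 was 2.72 without E11 fish 6 (limma adjusted p = 0.0695). In all, 4983 of 39705 probes passed, 2458 higher and 2525 lower, with 532 and 690 changed at least 2-fold and 55 and 27 at least 4-fold. The count was 3279 with only the PBS fish numbered 4 to 6 as controls, and without the loess step 69.0% instead of 49.3% of the probes were higher.

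LOLS15965 and LOLS11685 changed in the same direction under both strains at 6 dpi: LOLS15965 by -5.48 (limma adjusted p = 4.79e-08) and LOLS11685 by 4.87 (limma adjusted p = 1.61e-08) in Mma20 fish. The comparisons of Mma20 and E11 fish with PBS at 6 dpi had 2525 probes past the threshold in both, of which 1301 were higher in both and 800 lower in both, against 474.4 and 353.3 expected of independent lists. Another 424 went in opposite directions, 242 of them higher in Mma20 and lower in E11 fish, fewer than the 831.3 expected of independent lists. Simulated unchanged groups with 6 shared controls gave 0 probes past the threshold in both. That count decides nothing, since the adjusted p lets almost no probe pass where nothing changed. The fold changes of the 2 strains correlated across probes at 0.238, below the 0.337 of simulated unchanged groups, while their covariance of 0.0868 lay above the simulated 0.0216. With the PBS fish split between the comparisons, 1297 or 1706 probes passed in both.

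At 1 dpi, A_15_P102047 was already higher in Mma20 fish, by a log2 fold change of 5.32 (SE 0.66, limma adjusted p = 0.000179), with 3 of 3 Mma20 fish above every PBS fish; in the Cy5 channel alone it was higher by 4.46 (SE 0.53, limma adjusted p = 0.00013). Probe LOLS00194 rose by 5.75 in the fit (SE 1.64, limma adjusted p = 0.0495), at least 34.9-fold, since it was well above background in 0 of the 6 PBS fish. That bound sets the mean of the 3 Mma20 fish against the lowest signal well above background in the Cy5 channel, after loess and Aquantile normalization, and is open to dye bias without dye swaps. On LOLS00194 only 2 of the 3 Mma20 fish exceeded every PBS fish, and without Mma20 fish 1 the bound was 15.9-fold (limma adjusted p = 0.266), without fish 3 17.7-fold (limma adjusted p = 0.231) and without fish 2 151-fold. Probe A_15_P111059 fell by 3.87 on the log2 scale in the fit (SE 0.73, limma adjusted p = 0.00388). Only 1 of the 3 Mma20 fish was well above background on it, and their log2 ratios ran from -6.31 to -0.82, so the size of this fall is uncertain. LOLS15965 fell by 3.40 (SE 0.40, limma adjusted p = 0.000131). Mma20 infection at 1 dpi gave 2393 of 39705 probes past the threshold, 1230 higher and 1163 lower, with 458 and 230 changed at least 2-fold. The count was 1234 without Mma20 fish 1 of 1 dpi, 1540 without fish 3 and 1017 without the loess step, and with the ratio of Feature Extraction 48.3% instead of 51.4% of the probes were higher.

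In E11 fish of 1 dpi, A_15_P105472 was higher than in PBS fish by 3.41 on the log2 scale (SE 0.56, limma adjusted p = 0.00147, 5 of the 6 PBS fish well above background). LOLS09921 was higher by 3.35 (SE 0.27, limma adjusted p = 1.08e-05). LOLS09921 has the sequence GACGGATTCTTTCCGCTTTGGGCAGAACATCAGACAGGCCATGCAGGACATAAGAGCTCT, and its log2 ratio was 2.92 ± 0.20 (SD, n = 3) in E11 fish of 1 dpi, 2.35 ± 0.16 (SD, n = 3) in Mma20 fish of 1 dpi and -0.44 ± 0.44 (SD, n = 6) in PBS fish. LOLS15965 was lower, with a log2 fold change of -4.22 (SE 0.40, limma adjusted p = 2.61e-05), and so was LOLS11263 with -3.56 (SE 0.90, limma adjusted p = 0.0237). All 3 E11 fish lay beyond all 6 PBS fish on each of these 4 probes, but the adjusted p of LOLS11263 was 0.0673, 0.067 and 0.0905 without E11 fish 1, 2 and 3. In all, 2821 of 39705 probes passed, 1413 higher and 1408 lower, with 339 and 359 changed at least 2-fold. The count was 1705 without E11 fish 1 of 1 dpi and 1480 without fish 3, and without the loess step it was 1293, with 63.6% instead of 50.1% higher, while with the ratio of Feature Extraction 43.8% were higher.

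The 2 strains gave largely overlapping lists at 1 dpi. Both comparisons with PBS had 1450 probes past the threshold, 608 higher in both and 842 lower in both, with 0 in opposite directions. Independent lists would give 43.8 higher and 41.2 lower. Simulated unchanged groups gave 0, which decides nothing since the adjusted p lets almost no probe pass where nothing changed. The fold changes of the 2 strains had a covariance of 0.0975 against a simulated 0.0214. Their correlation across probes was 0.607 against 0.334. With the PBS fish split between the comparisons, 706 or 669 probes passed in both. PBS and infected fish shared no slide, so an effect of the slides would also be common to both lists. Over all 4 comparisons with PBS, 429 probes were higher in each and 406 lower in each, LOLS11685 and LOLS09921 among the former and LOLS15965 among the latter.

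**Figure D2:**
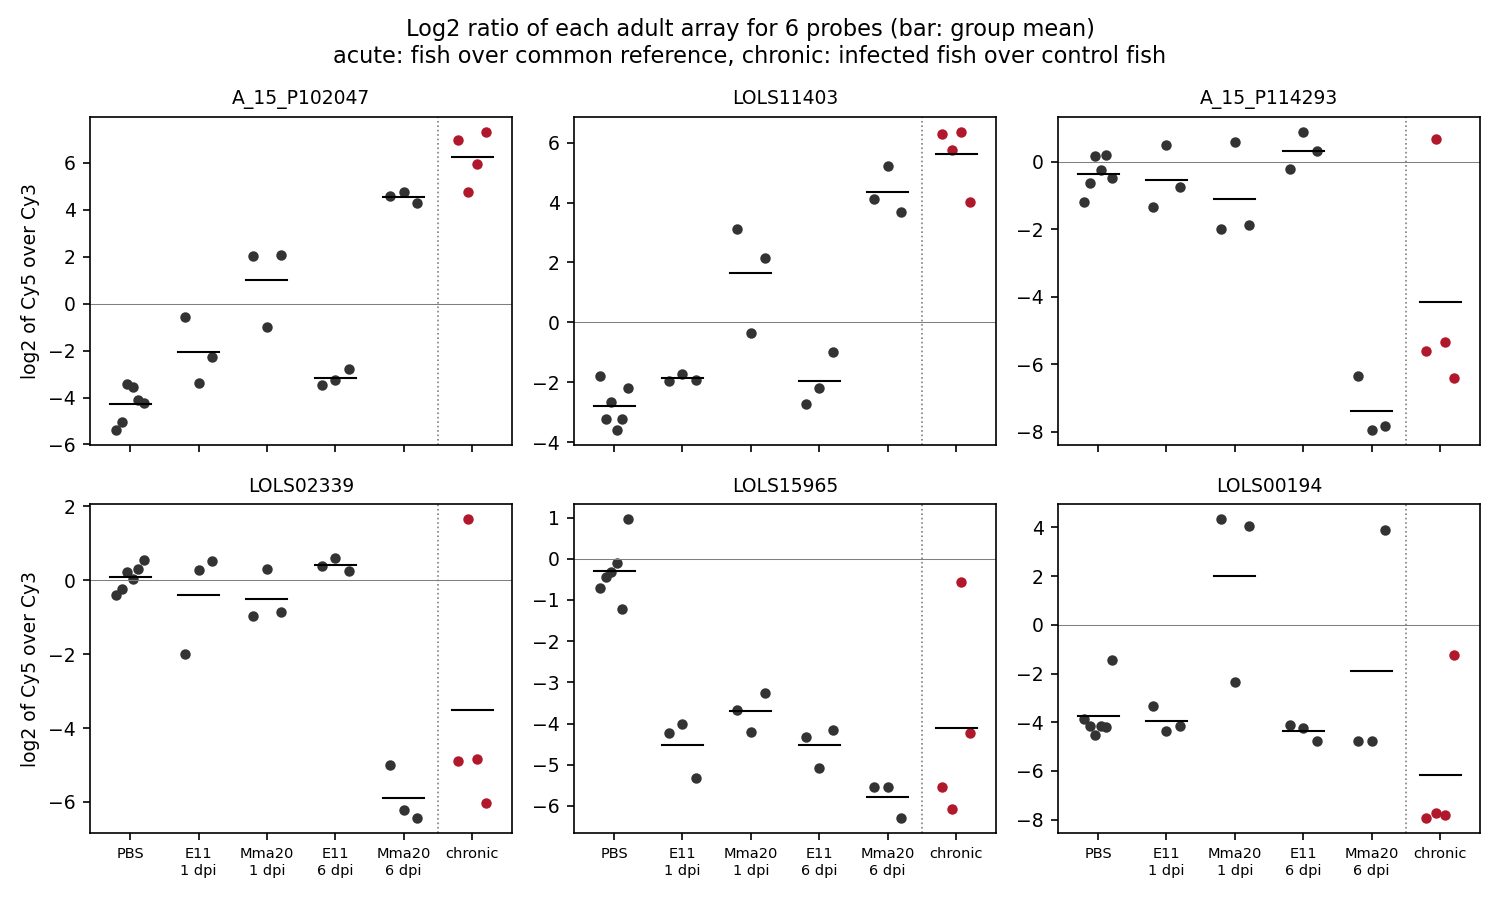
Log2 ratio of Cy5 over Cy3 (vertical axis) of every adult array for 6 probes, by group (horizontal axis), with 1 point per array and a bar at the group mean. Acute fish are set against the common reference and chronic fish against a control fish, so the levels of the chronic arrays are not on the same baseline; A_15_P102047 has a mean of 4.54 in Mma20 fish of 6 dpi and -4.29 in PBS fish.

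Setting the strains against each other directly, Mma20 fish of 6 dpi differed from E11 fish of 6 dpi on probes with very large changes. A_15_P102047 was higher by a log2 fold change of 7.72 (SE 0.76, limma adjusted p = 1.96e-06). A_15_P111645 was higher by 6.62 (SE 0.43, limma adjusted p = 2.86e-08), with a log2 ratio of 3.87 ± 0.21 (SD, n = 3) in Mma20 fish and -2.75 ± 0.35 (SD, n = 3) in E11 fish. The mean normalized log2 Cy5 signal of A_15_P102047 was 16.9 in Mma20 and 12.7 in E11 fish, a smaller difference than that of its ratio, and that of A_15_P111645 was 14.2 and 7.83. A_15_P114293 was lower by a log2 fold change of -7.71 (SE 0.64, limma adjusted p = 3.48e-07). LOLS02674 was also lower by -7.71 (SE 2.01, limma adjusted p = 0.00818), but it varied strongly among PBS fish as well. In this comparison 11460 of 39704 probes passed, 6273 higher and 5187 lower in Mma20 fish, with 2879 and 2456 changed at least 2-fold. No slide held both groups. A fit of the 12 infected fish gave 9821 probes without the slide and 1033 with it as a fixed block, 698 higher and 335 lower, and the fold changes of these fits correlated across probes at 0.824. With the block, A_15_P102047 had a log2 fold change of 6.02 (limma adjusted p = 0.0837) and LOLS02674 of -6.97 (limma adjusted p = 0.312), and neither passed. The count was 7622 in a fit of these 6 fish alone, and with the ratio of Feature Extraction 48.1% instead of 54.7% of the probes were higher.

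At 1 dpi the strains differed on 60 of 39705 probes, 44 higher and 16 lower in Mma20 fish. A_15_P114842 was higher by a log2 fold change of 4.60 (SE 0.72, limma adjusted p = 0.0248) and LOL02334 by 3.55 (SE 0.60, limma adjusted p = 0.0354). The log2 ratio of LOL02334 lay between 1.3 and 4.26 in the 3 Mma20 fish, and between -0.56 and -0.27 in the 3 E11 fish. LOLS05030 was lower by -1.66 (SE 0.31, limma adjusted p = 0.048) and A_15_P109328 by -1.59 (SE 0.28, limma adjusted p = 0.0374). All 4 probes lost their call with the slide as a random or fixed block and in a fit of these fish alone. With the fixed block A_15_P114842 had a log2 fold change of 3.88, LOL02334 of 1.60, LOLS05030 of -1.52 and A_15_P109328 of -0.93 (limma adjusted p = 0.298, 0.544, 0.365 and 0.505). Without E11 fish 3, Mma20 fish 1 or Mma20 fish 3 of 1 dpi their adjusted p was 0.119 to 0.246. This count was fragile: in the 12 infected fish it was 1 without the slide and 2 with it as a fixed block. It was 5 in all acute fish with the slide as a random block, 7 without the loess step (6 higher and 1 lower) and 2 in a fit of these fish alone. Leaving out E11 fish 1 or 3 of 1 dpi gave 11 and 2, Mma20 fish 1 or 3 of 1 dpi 5 and 3, Mma20 fish 5 of 6 dpi 27, and PBS fish 1, 2, 4, 5 or 6 gave 22, 24, 29, 22 and 21. Without E11 fish 2 of 1 dpi it was 220, with 43 higher and 177 lower, so that most probes were then lower, and without Mma20 fish 2 of 1 dpi 93.

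The strain difference itself changed between the days. The interaction of strain and day passed for 4965 of 39704 probes, 2987 positive and 1978 negative. A_15_P102047 had an interaction of 4.63 (SE 1.07, limma adjusted p = 0.0102), A_15_P114293 of -7.15 (SE 0.91, limma adjusted p = 0.000128) and LOLS02339 of -6.21 (limma adjusted p = 9.09e-05), while LOLS11403 with 2.80 (limma adjusted p = 0.0802) did not pass. From the Cy5 channel alone A_15_P102047 had an interaction of 1.95 (SE 0.86, limma adjusted p = 0.204) and did not pass, A_15_P114293 had -6.84 (limma adjusted p = 6.61e-05) and LOLS02339 -5.78 (limma adjusted p = 7.69e-05). The highest interactions past the threshold were 4.98 for LOL02520 (limma adjusted p = 1.7e-05) and 4.92 for LOL02515 (limma adjusted p = 1.29e-05). Both passed from the Cy5 channel alone, with 3.57 (limma adjusted p = 5.68e-05) and 3.45 (limma adjusted p = 1.64e-05). Next to A_15_P114293 among the lowest was A_15_P110090 with -6.46 (limma adjusted p = 9.13e-05), and -5.75 (limma adjusted p = 7.38e-05) from the Cy5 channel alone. With the slide as a fixed block, A_15_P114293 had an interaction of -5.82 (limma adjusted p = 0.0712) and A_15_P110090 of -6.24 (limma adjusted p = 0.0565), and both no longer passed. The count was 1148 with the slide as a fixed block among the infected fish, 3209 in a fit of those fish alone and 3089 on the Cy5 channel alone.

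In the ratios, fish with overt chronic tuberculosis showed their highest rises on the same pair of probes as Mma20 fish of 6 dpi, where the Cy5 channel alone ranked A_15_P102047 lower. A_15_P102047 was higher than in the control fish by a log2 ratio of 6.26 ± 1.16 (SD, n = 4; limma adjusted p = 0.00891) and LOLS11403 by 5.61 ± 1.09 (SD, n = 4; limma adjusted p = 0.00891). LOLO1753 was lowest at -6.39 ± 1.73 (SD, n = 4; limma adjusted p = 0.0109), followed by LOLS00194 at -6.18 ± 3.30 (SD, n = 4; limma adjusted p = 0.0309). LOLO1753 also lay between -7.40 and -4.10 on all 18 acute arrays, PBS fish included, in the deposited ratios. A_15_P114293 and LOLS02339 averaged -4.16 ± 3.26 and -3.52 ± 3.49 (SD, n = 4) and did not pass (limma adjusted p = 0.0723 and 0.12), with chronic pair 2 apart from the other pairs on both. In all, 9921 of 43370 probes passed, 5336 higher and 4585 lower, with 3265 and 2876 changed at least 2-fold. Infected fish always carried Cy5, so the dye bias of a probe stays in its ratio here, and the scale and direction of these deposited ratios rest on the labels. The count depends on each pair: it was 0 without pair 1, 1513 without pair 2, 1231 without pair 3 and 5586 without pair 4, and 14984 when each probe's mean acute ratio was subtracted as an estimate of its dye bias. Without pair 1 the adjusted p of both A_15_P102047 and LOLS11403 was 0.0525. That of LOLO1753 was 0.0525, 0.0514 and 0.0525 without pairs 1, 2 and 3, and that of LOLS00194 was 0.108, 0.115 and 0.103. After the subtraction A_15_P102047 had a log2 ratio of 7.58 (limma adjusted p = 0.00226), LOLS11403 of 6.14 (limma adjusted p = 0.0029), LOLO1753 of -0.62 (limma adjusted p = 0.506) and LOLS00194 of -0.76 (limma adjusted p = 0.668).

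The groups of probes found in the acute fish were then followed in the chronic fish, with which they share no control. Of the 3213 probes at least 2-fold higher in Mma20 fish of 6 dpi, 94.9% were also higher in chronic fish, with a median log2 ratio of 1.17, and 2053 passed there in the same direction. Of the 1904 probes at least 2-fold lower, 97.2% were lower in chronic fish, with a median of -1.30, and 1085 passed. In single chronic pairs the shares ran from 90.4% to 93.7% for the higher group and from 90.1% to 95.1% for the lower group. The groups of E11 fish of 6 dpi kept their sign in 60.3% of 532 higher and 73.0% of 690 lower probes, and in single chronic pairs in 52.8% to 65.2% and 48.4% to 88.1%. Mma20 groups of 1 dpi kept it in 85.6% of 458 and 89.1% of 230 probes, and E11 groups of 1 dpi in 61.4% of 339 and 72.7% of 359. In single pairs these shares ran from 68.6% to 91.0% and 67.0% to 90.9% for Mma20 groups of 1 dpi, and from 50.7% to 65.8% and 41.5% to 88.0% for E11 groups of 1 dpi. Across probes, chronic fold changes correlated with those of Mma20 fish of 6 dpi at 0.711 (covariance 0.484), of Mma20 fish of 1 dpi at 0.275, of E11 fish of 6 dpi at 0.0952 and of E11 fish of 1 dpi at 0.0893.

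**Figure D3:**
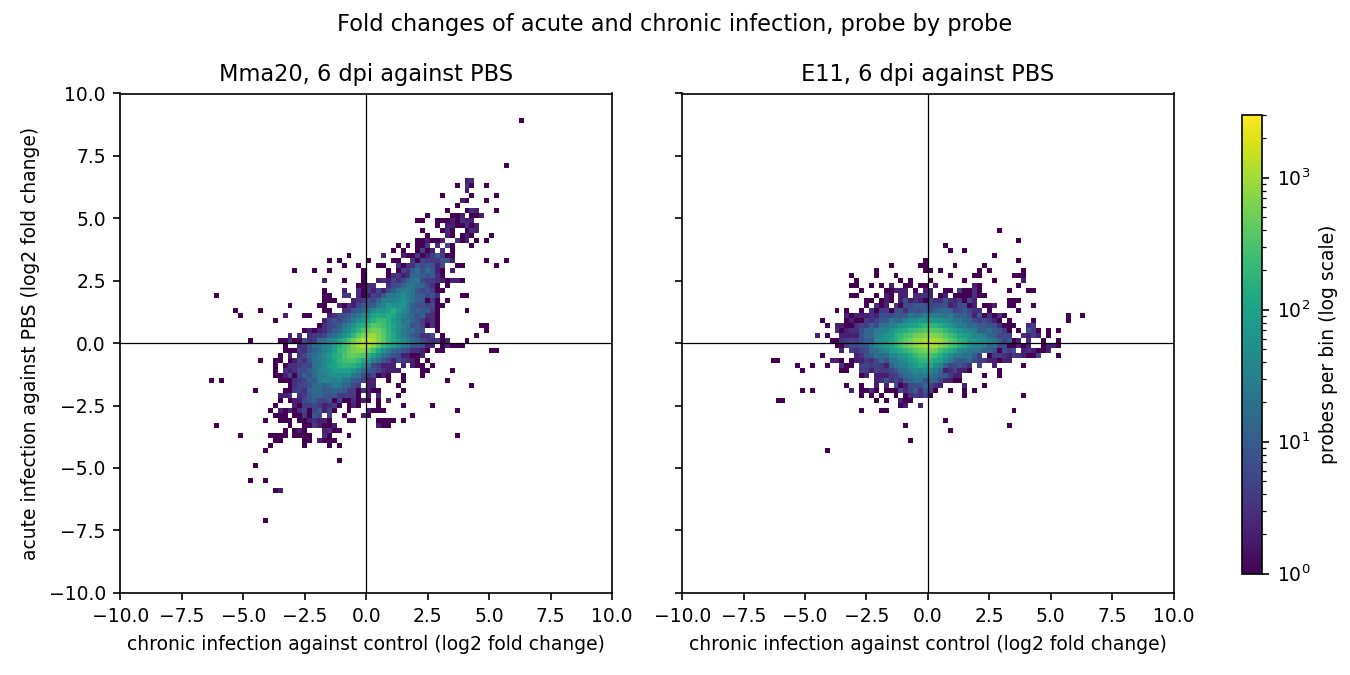
Log2 fold change of chronic infection against control (horizontal axes) and of acute infection at 6 dpi against PBS (vertical axes), with the number of probes per bin in colour on a log scale. Points of Mma20 fish on the left lie along the diagonal, with a correlation across probes of 0.711, and those of E11 fish on the right do not, with 0.0952.

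Tested directly on the deposited ratios of both experiments, the chronic response differed from the 6 dpi response to Mma20 on 1742 of 43370 probes, 974 higher and 768 lower. It differed from the 6 dpi response to E11 on 10720 probes, 5470 higher and 5250 lower. With each array centred on its median, most probes were lower instead, 849 higher and 925 lower for Mma20 and 5143 and 5479 for E11. The former count was 683 without Mma20 fish 4 of 6 dpi and 915 without fish 5. Dye bias cancels in the acute differences but not in the chronic ratios, and experiment and disease stage cannot be told apart in either comparison.

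In embryos no probe passed an adjusted p of 0.05 in limma between E11 and PBS at 2, 24 or 120 hpi, and 1320, 4577 and 1464 of 43370 probes had an unadjusted p below 0.05. E11 pools A and B of 2 hpi correlated across probes at 0.208, and E11 pool C of 24 hpi with its pools A and B at 0.256 and 0.148. PBS pools of the same time correlated at 0.471 to 0.93. The lowest adjusted p was 0.697 at 2 hpi for LOLS12341, whose log2 fold change was -2.53 (SE 0.38), 0.425 at 24 hpi for A_15_P117374 with -2.13 (SE 0.33), and 0.189 at 120 hpi for A_15_P102283 with 3.08 (SE 0.43). LOLO1753 had a log2 fold change of -1.80 (SE 0.26, limma adjusted p = 0.189) at 120 hpi. The adult probes A_15_P102047 and LOLS11403 had log2 fold changes of -0.86 (SE 1.12) and 0.13 (SE 0.40) at 120 hpi, both with a limma adjusted p of 1. The median SE of a log2 fold change was 0.528 at 2 hpi and 0.472 at 24 and 120 hpi, against 0.181 for the adult comparisons with PBS. In simulated data, 22% to 36% of probes changed by 2 on the log2 scale were recovered at these times. Of those changed by 3, 52% to 74% were recovered, so real changes of this size may have been missed. Without E11 pool A of 2 hpi 366 probes passed at 2 hpi and 12 at 24 hpi, without E11 pool B of 2 hpi 4 and 12, without E11 pool B of 120 hpi 1 at 2 hpi and 1 at 120 hpi, and without PBS pool C of 2 hpi 1 at 2 hpi.

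The adult groups were also tested as sets in the embryos with camera, 10 sets per time. At 120 hpi, the 532 probes higher in E11 adults of 6 dpi were shifted down, with a median log2 fold change of -0.35 against -0.01 for all probes (adjusted p = 2.4e-09 with the preset correlation, adjusted p = 0.0255 with an estimated correlation). The other 7 calls at 120 hpi, all downward, were lost with an estimated correlation, where the lowest adjusted p was 0.0591. They held adult groups of both directions, such as the probes lower in E11 adults of 6 dpi, with a median of -0.22. The downward shift was therefore not limited to groups that were higher in adults. At 2 and 24 hpi no set passed (lowest adjusted p = 0.0734 and 0.0651 with the preset correlation).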

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

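The tests of the slide, the dyes and the strain for the large Mma20 response, of chance values of the shared PBS fish, of slides as the whole cause of the shared changes, and of the infection seen in both Mma20 and chronic fish and of dye bias as the whole cause there were chosen after the result was seen, and the chronic pattern replaced another, on the reference channel, whose values had been seen.

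A single sample lay far from the others of its group for 7 values among 55 groups tested, where chance gives about 5% of groups. Only values of PBS and chronic fish were tested, since the infected acute groups and the embryo groups held too few samples for this rule. Chronic pair 2 had a log2 ratio of 0.68 on A_15_P114293, where the nearest other pair had -5.34, and of 1.65 on LOLS02339, where the nearest had -4.84. Chronic pair 4 had -1.24 on LOLS00194 (nearest -7.74), -0.69 on LOLS05030 (nearest -1.46) and -0.34 on A_15_P109328 (nearest -1.87). PBS fish 6 had -1.45 on LOLS00194 (nearest -3.87), and PBS fish 3 had -2.64 on LOLS11263 (nearest -0.13).

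Direct tests in limma gave differences between the strains and between the chronic and acute experiments, in which experiment and disease stage cannot be told apart. The strain difference at 6 dpi passed for 11460 probes and the interaction of strain and day for 4965. Chronic infection differed from the 6 dpi response to Mma20 on 1742 probes and from that to E11 on 10720. Among the probes named in the comparisons with PBS, the interaction was 4.63 for A_15_P102047 (adjusted p = 0.0102), -7.15 for A_15_P114293 (adjusted p = 0.000128), -6.21 for LOLS02339 (adjusted p = 9.09e-05), -2.09 for LOLS15965 (adjusted p = 0.0471), 3.21 for A_15_P105472 (adjusted p = 0.0303) and -5.64 for LOLS11263 (adjusted p = 0.0187). From the Cy5 channel alone, chosen after the result was seen, A_15_P102047 with 1.95 (adjusted p = 0.204), LOLS15965 with -2.09 (adjusted p = 0.0503) and A_15_P105472 with 2.78 (adjusted p = 0.0832) did not pass.

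Mma20 fish of 6 dpi stood apart at 113 to 131 on the first principal component, and all 3 lay on 1 slide, while Mma20 fish 3 of 1 dpi on the same slide lay at 7.76. Of the probes called there with at least a 2-fold change, 95.8% kept their sign in the chronic arrays, which were not on that slide since its 4 positions held other arrays, and this argues against the slide as the whole cause. Of the called probes, 75.5% were called again in the same direction from the Cy5 channel alone. Most calls therefore did not rest on the reference channel alone. The Cy5 signal would change with or without competition of the dyes, so this share does not decide on that competition. With the slide as a fixed block among the 12 infected fish, Mma20 and E11 fish of 6 dpi still differed on 1033 probes, as an effect of the Mma20 strain requires and a slide effect equal on all its arrays does not give. The slide of the Mma20 fish of 6 dpi was tied to the other infected slides only through Mma20 fish 3 of 1 dpi. The correction for that slide therefore rests on this single fish. The slide may still account for part of the strain difference. Without the block that difference passed for 9821 probes in these fish, with a correlation of 0.824 between the fold changes of both fits.

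E11 fish and Mma20 fish of 1 dpi shared many changes against PBS. The covariance of the fold changes of E11 fish of 6 and 1 dpi was 5.83 times the simulated one, which argues against chance values of the shared PBS fish. Of the 1308 probes called the same way in these 3 comparisons, 76.7% had the same sign in chronic fish (95% exact binomial interval 74.3 to 78.9%, which treats probes as independent). In single pairs it was 58.1% to 86.1%, and all probes in these directions give 50.1%. These probes had to be called in Mma20 fish of 1 dpi, whose groups kept their sign in chronic fish in 85.6% and 89.1%. Of the 835 also called the same way in Mma20 fish of 6 dpi, 91.9% kept it. This choice of probes can raise the share by itself, so the share does not decide on slides for the shared changes. Of the 430 of the 1308 probes not called in Mma20 fish of 6 dpi, 53.7% had the same sign (29.6% of 81 higher and 59.3% of 349 lower probes). Leaving out the probes called there removes those that ran with chronic fish, so this share decides nothing. For these 430 probes slides and infection cannot be told apart, since PBS and infected fish shared no slide.

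Chronic fish were infected with E11 per the design text, yet their changes ran with those of Mma20 fish of 6 dpi. Of the probes called in chronic fish with at least a 2-fold change and measured in both, 2917 higher and 2686 lower, 92.8% had the same sign in Mma20 fish of 6 dpi against PBS, as a response to infection common to both requires. Of all 9131 probes called in chronic fish and measured in both, 91.0% had the same sign there, and since dye bias cancels in that difference, this argues against dye bias as the whole cause. After each probe's mean acute ratio was subtracted, which is not dye bias alone since the reference held RNA of infected fish, 53.0% of the 9921 probes stayed called in the same direction, so for single probes of the remainder dye bias and infection cannot be told apart. One candidate explanation is a state of advanced disease common to both groups, which the design does not test.

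Other splits of the same arrays were fitted without the remaining groups. For the comparisons with PBS, 1 of 84 splits, the real one, reached the real count in each. The counts were 14196 probes for Mma20 6 dpi (highest other 41), 4186 for E11 6 dpi (328), 2724 for Mma20 1 dpi (7) and 2521 for E11 1 dpi (8). This argues against a chance split. Only the real split parts the slides of PBS fish from those of infected fish, so it does not tell infection from the slides. For chronic infection against the acute responses, the acute ratios entered minus the mean of the PBS fish, and 1 of 35 splits reached the real count for Mma20 (985 probes, highest other 2) and for E11 (6480 and 7). Only the real split parts the experiments, and the shared PBS mean also goes with it, so these splits do not bear on a difference of the responses. For the interaction, 2 of 100 splits reached the real 3209 probes. This share tells how rarely a split keeps the 3 Mma20 fish of 6 dpi together: the 2 other splits drawn that did gave a highest of 3823 and a median of 3480, and splits that did not reached at most 112. The splits therefore point to those 3 fish as the main structure among the infected fish, and do not exclude chance for the grouping by strain and day beyond them. With the slide as a fixed block 1148 probes passed.

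The splits were too few for a share under 0.05 in the remaining comparisons. Mma20 against E11 gave 7622 probes at 6 dpi (1 of 10 splits, highest other 3) and 2 at 1 dpi (2 of 10, highest other 3). Chronic infection gave 9921 (1 of 8 sign changes, highest other 0). Embryos gave 0 at 24 hpi (10 of 10, highest other 0) and 0 at 120 hpi (10 of 10, highest other 3394). The split with 3394 probes set E11 pool A and PBS pools B and C of 120 hpi against the other 3 pools. It points to a structure of these pools other than infection. A block for the embryo arrays with a scanner file left the embryo count at 0.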

How the results depend on the processing

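The slide as a fixed block, the Cy5 channel alone and the subtraction of mean acute ratios were chosen after the result was seen. The embryo block for arrays with a scanner file and the joint omission of 2 embryo arrays were too.

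The count for Mma20 against PBS at 6 dpi stayed between 10030 and 13239 in all settings that kept every array, and was 14196 in a fit of these groups alone. Among 1017 values of named probes under alternatives, 893 kept their direction and side of the threshold, 117 no longer passed, 7 newly passed and 0 changed sign. LOLS00194 in Mma20 fish of 1 dpi lost its call in 18 alternatives, A_15_P116757 in 6, LOLS11263 in 5, and the 4 probes named for the strains at 1 dpi in 10 to 22. The cause was not tested unless stated. Median centring without loess gave 1017 probes for Mma20 and 1293 for E11 against PBS at 1 dpi and 7 for the strains at 1 dpi; the share of higher probes was then 71.1% instead of 58.0% for Mma20 at 6 dpi, 69.0% instead of 49.3% for E11 at 6 dpi, 63.6% instead of 50.1% for E11 at 1 dpi and 85.7% instead of 73.3% for the strains at 1 dpi. With the ratio of Feature Extraction, 5856 probes were higher and 6089 lower for Mma20 at 6 dpi, 4969 and 5354 for the strains at 6 dpi, 947 and 1013 for Mma20 at 1 dpi and 1078 and 1383 for E11 at 1 dpi, so most were then lower. Median centring of each array did the same for chronic infection against the Mma20 (849 and 925) and E11 (5143 and 5479) responses. Without loess, 2438 were higher and 1096 lower for E11 at 6 dpi. The slide as a random block gave 5 for the strains at 1 dpi; as a fixed block among the 12 infected fish it gave 1033 for the strains at 6 dpi, 2 at 1 dpi and 1148 for the interaction. PBS fish 4 to 6 alone gave 3279 for E11 at 6 dpi, with fewer controls. Fits of only the groups compared, with fewer arrays, gave 7622 for the strains at 6 dpi, 2 at 1 dpi and 3209 for the interaction. The Cy5 channel alone gave 3089 for the interaction, and subtracted mean acute ratios 14984 for chronic infection. Without E11 pool C of 24 hpi and E11 pool B of 2 hpi, 4 probes passed at 2 hpi and 12 at 24 hpi. With PBS fish 1, 3 and 5 against 2, 4 and 6, 1297 probes passed for both strains at 6 dpi.

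With the replicate number as a block, 2557 probes passed for E11 at 6 dpi, 1000 for Mma20 and 1387 for E11 at 1 dpi, and 7 for the strains at 1 dpi; embryos stayed at 0. The deviations gave little sign that the numbers pair the samples. Those of same-numbered adult fish correlated at -0.267 to 0.126 and those of same-lettered embryo pools at -0.548 to 0.261. Not every sample correlated best with its own number, but the letters of the embryo pools may still mark infection days.

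Each array left out in turn gave 10274 to 14264 probes for Mma20 and 3667 to 5099 for E11 at 6 dpi, 1234 to 2948 for Mma20 and 1480 to 3337 for E11 at 1 dpi, 9023 to 11700 and 2 to 220 for the strains at 6 and 1 dpi, and 3554 to 4821 for the interaction. Mma20 at 1 dpi had 1234 without its fish 1 and 1540 without fish 3, E11 at 1 dpi 1705 without fish 1 and 1480 without fish 3. The strains at 1 dpi had 11, 220 (43 higher and 177 lower) and 2 without E11 fish 1, 2 and 3, 5, 93 and 3 without Mma20 fish 1, 2 and 3, 27 without Mma20 fish 5 of 6 dpi, and 22, 24, 29, 22 and 21 without PBS fish 1, 2, 4, 5 and 6. Chronic infection had 0 to 5586: 0, 1513, 1231 and 5586 without pairs 1, 2, 3 and 4. Chronic against the Mma20 response had 683 to 2164, with 683 without Mma20 fish 4 and 915 without fish 5, and against the E11 response 7744 to 10911. Embryos had 0 to 366 at 2 hpi, 0 to 12 at 24 hpi and 0 to 1 at 120 hpi. Without E11 pool A of 2 hpi they had 366 at 2 hpi and 12 at 24 hpi, without its pool B 4 and 12, without E11 pool B of 120 hpi 1 at 2 and 1 at 120 hpi, and without PBS pool C of 2 hpi 1 at 2 hpi. The lone E11 pool left at 2 hpi was then assumed to vary like the other groups.

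Gene list tests and their alternatives were not run, since no probe carries a gene name. Signal over background limits 3665 probes, which were not tested on the acute arrays.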

Other observations

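All values in this part were chosen after the data were seen.

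Between the days, more probes changed in Mma20 fish than in E11 fish. Mma20 fish of 6 dpi differed from those of 1 dpi on 8466 probes, 5095 higher and 3371 lower, in limma. E11 fish differed between the days on 11 probes, 6 higher and 5 lower. In a fit of the 12 infected fish these counts were 6595 and 0 (2868 E11 probes had an unadjusted p below 0.05), and 2511 and 4 with the slide as a fixed block. Within slide 9, Mma20 fish 4 to 6 of 6 dpi differed from fish 3 of 1 dpi on 3931 of 39676 probes, 2444 higher and 1487 lower, and within slide 7, E11 fish 4 of 6 dpi differed from fish 1 to 3 of 1 dpi on 157, 59 higher and 98 lower, with the lone fish taken to vary like the others. E11 fish 4 had a mean correlation of 0.661 with its own group, the lowest of the acute arrays. The day and the lone fish cannot be told apart within either slide. The interaction tests the difference between the strains. A_15_P102047 averaged 1.03 ± 1.75 (SD, n = 3) in Mma20 fish of 1 dpi and 4.54 ± 0.23 (SD, n = 3) at 6 dpi, and in E11 fish -2.06 ± 1.41 and -3.18 ± 0.35 (SD, n = 3 each). Its rise in Mma20 fish was 3.51 in the ratio and 0.95 (SE 0.61, limma adjusted p = 0.356) in the Cy5 channel alone. The rest lay in the signal of the reference, which held the same RNA on every acute array. Why that signal fell was not tested, so the size of the rise stays open. A_15_P111645 averaged 0.60 ± 0.82 and 3.87 ± 0.21 in Mma20 fish and -2.14 ± 0.37 and -2.75 ± 0.35 in E11 fish (SD, n = 3 each), a rise in Mma20 fish of 3.16 in the Cy5 channel alone (SE 0.40, limma adjusted p = 5.75e-05), and 4.81 ± 1.49 (SD, n = 4) in chronic fish.

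Embryo age moved more probes than infection. PBS pools of 120 hpi differed from those of 2 hpi on 8424 probes (4357 higher and 4067 lower) and from those of 24 hpi on 4689 (2665 higher and 2024 lower), and pools of 24 hpi differed from those of 2 hpi on 100 (69 higher and 31 lower). E11 pools of 120 hpi differed from those of 2 hpi on 6561 probes.

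Probes called in opposite directions by the strains at 6 dpi mostly had the Mma20 direction in chronic fish. Of the 242 higher in Mma20 and lower in E11 fish, 87.6% were higher in chronic fish and 45 passed. Of the 182 lower in Mma20 and higher in E11 fish, 97.8% were lower in chronic fish and 94 passed. LOLS09921, higher in all 4 acute comparisons, had a chronic log2 ratio of 0.06 (SE 0.37, limma adjusted p = 0.928), and differed from the acute response to E11 at 6 dpi by -2.94 (limma adjusted p = 0.000163). LOLS11685 was higher in chronic fish too, by 2.88 (SE 0.61, limma adjusted p = 0.0328), and LOLS15965 was lower, by -4.10 (SE 0.97, limma adjusted p = 0.0413).

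In the reference channel, which held the same RNA on every acute array, signals moved against the sample on bright probes. Of 448 probes with at least a 4-fold change in Mma20 fish of 6 dpi and a brighter group mean over 14 on the log2 scale, 98.2% had a normalized Cy3 change opposite to the fold change, and 99.1% a raw one. Of 387 probes from 12 to 14 it was 83.4% (72.1% raw), and of 308 probes under 12 it was 60.1% (60.7% raw). The raw share was 63.9% for higher and 98.9% for lower probes from 12 to 14, and 51.3% and 86.6% under 12, so most raw signals of lower probes moved against the sample at each brightness. The ratio of such bright probes therefore held a change of the reference signal as well, and the Cy5 channel alone gave 10462 called probes for Mma20 at 6 dpi, 9986 of them shared with the ratio.

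Some probes had a large mean ratio with 1 sign in every acute fish. Of 43370 probes, 446 had a mean acute ratio of at least 3 on the log2 scale, in either direction, and 1 sign on all 18 acute arrays; 168 of them were called with the same sign in chronic fish and 14 with the opposite sign, and 365 had the same sign in the mean embryo ratio. Across probes, the mean acute ratio correlated at 0.345 with the chronic log2 ratio and at 0.319 with the mean embryo ratio. LOLO1753 lay between -7.40 and -4.10 on the acute arrays and between -0.55 and 2.97 on the embryo arrays.

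Individual fish differed widely on a few probes: 125 had a range of at least 4 on the log2 scale over the 6 PBS fish. LOLS02674 lay between -5.46 and 1.93 in PBS fish, between -5.51 and 2.48 in E11 fish of 1 dpi, between 1.39 and 1.62 in E11 fish of 6 dpi and between -6.32 and -6.03 in Mma20 fish of 6 dpi. Of the 125 probes, 6 passed for Mma20 against PBS at 6 dpi and 14 for Mma20 against E11 at 6 dpi.

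Probes with neighbouring identifiers moved together in some classes. The median correlation over the acute arrays with the next identifier was 0.514 for LOL0, 0.546 for LOLG, 0.593 for LOLO and 0.71 for LOLC probes, against 0.0151 for LOLS and 0.0114 for A_15 probes. For 224 pairs of identifiers that share 1 sequence, the SD of the difference in log2 ratio on the same array was 0.143, and 0 pairs differed by over 0.5 in the fold change of Mma20 fish of 6 dpi.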
